A study of Mus musculus with 50 samples.

How the data were processed

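The data were 3′ end poly(A) RNA-seq of mouse embryonic stem cells of the KH2 line, a C57BL/6 x 129/Sv hybrid, in 5 genotypes. WT cells were compared with knockouts of Ythdf1, Ythdf2 or Ythdf3, called Ythdf1_KO, Ythdf2_KO and Ythdf3_KO, and with a knockout of all 3 genes, called Triple_KO. The 3 genes encode YTH-domain proteins that bind N6-methyladenosine (m6A), a base modification of mRNA. Per the labels' protocols, the cells were kept in serum with LIF, plated on gelatin 48 h before treatment, given fresh medium with 5 µM actinomycin D, which blocks transcription, and collected in Trizol at 0, 4 and 8 h. Each genotype had replicates A and B. At 0 h and 8 h each replicate had 2 duplicate libraries and at 4 h it had 1, so that the 50 libraries formed groups of 4, 2 and 4 per genotype.

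The deposited values were in FPM, a count of reads for each RefSeq transcript scaled to the library total (the same unit as RPM), with no correction for length. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 and the mouse build mm10 were used. The name of the deposited table holds the words ESAT, a program that counts 3′ end reads, and filter. The treatment of reads with several matches, the use of strand, the annotation version and the filter's rule were not given in the sources used here. In all 50 libraries the low values were whole multiples of what 1 read is worth (0.427 to 1.25 FPM), and 100% of the values came out as whole reads within 0.1 read. The library totals recovered from this were 796921 to 2341410 reads, with a median of 1364120. The listed transcripts held less than the whole of each total, so the share of a library in the listed genes was itself measured. Values near the filter rest on few reads, which limits the precision of low genes. Because reads were counted near the 3′ end, a knockout that edits another part of a gene can leave reads in place. The edited parts were not given in the sources used here.

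The table held 22338 transcripts. Gene names were found for 21729 of them through the RefSeq gene table of GRCm38.p6, the same build as mm10, and for 120 through GENCODE M21, and 489 had none. Coordinates are those of GRCm38.p6. Transcripts of one gene often carried identical values in every library, and 2169 such repeats were dropped so that no read was added more than once. This departed from the plain sum planned. In 652 genes the distinct transcripts were summed, which gave 19455 genes. Of these, 2292 shared an identical value with another gene, and reads of close paralogs, pseudogenes and overlapping genes could not be told apart. No gene was listed at 0 in every library, and no transcript of the mitochondrial genome was listed, so that 1 of the planned gene lists was not analysed here.

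Duplicate libraries were averaged on the log2(FPM + 1) scale, which understates the change of low genes, and the replicate was the unit (n = 2 per genotype and time). The labels do not say that A and B were separate cultures. Genes with at least 5 FPM in at least 2 replicate means were tested with limma 3.58 (R 4.3), with empirical Bayes moderation, a mean-variance trend and Benjamini-Hochberg adjustment over the genes tested at 0.05. The levels at 0 h were fitted on the 10 replicate means of 0 h and the decay values on all 30. A decay value is log2 of the level at 8 h over that at 0 h, and its differences between genotypes were tested as a genotype by time term. All values are scaled to the library total and no spike-in was named in the labels, so every change is relative to that total. Errors of fold changes are standard errors from limma. Errors of FPM and shares are SD over libraries.

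In all, 31 gene lists written from general knowledge were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. Camera compares a list's test statistics, not fold changes, with other genes, so its direction can oppose the median. Fry tests any change. Benjamini-Hochberg adjustment was per comparison. List medians are log2 changes, for decay values also relative to that of all genes. Genes were grouped by structure from GENCODE M21, which covered 98.0% of the genes tested: an internal exon of at least 400 nt, the fifth of genes with the fewest exon junctions per kb, and the fifth with the longest 3′ UTR. Simulated unchanged groups that shared the WT libraries gave the similarity of knockout effects under chance. Gene structure, list tests, the 11 comparisons, the groups, the lists and the rule for naming genes were fixed before the data were examined.

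The genes named were the readers in every comparison, the 10 largest rises and the 10 largest falls for the WT time course and for Triple_KO, and the 5 largest of each for a single knockout. Each had to pass the test with the same sign in both replicates and reach a mean of 10 FPM in a group compared. Gene models without a name and pseudogenes were counted but not named. In addition the 2 members with the smallest p of each list described were named. Some genes that this rule names are not reported here. At most 8 called lists per comparison are described, those with the smallest p. This limit was set after the list results were seen, to bound the length. Where 5 or fewer genes changed in a direction, those outside the rule were named too, which was chosen after their values were seen.

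Alternatives planned were pseudocounts of 0.5 and 5 FPM, no filter, median and TMM scaling (the latter with edgeR 4.0), libraries kept separate with an estimated correlation between duplicates, transcripts kept as deposited, a replicate block, 4 h in place of 8 h, a straight line over the 3 times, a fit of the 0 h levels on all times, split WT replicates, and each replicate left out in turn. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads, the highest transcript per gene, the omission of chromosome 13 genes, genes over 20 FPM, and the overlap of calls with the WT replicates split. Python 3.11 with numpy 2.4, pandas 2.3 and matplotlib 3.10 was used for the rest.

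The tests were tested on simulated data with 200 changed genes. For the WT time course (8502 genes), limma recovered 20% of the genes changed 1.5-fold, 70% at 2-fold, 92% at 3-fold and 94% at 4-fold, and 6 of the 149 genes called were unchanged. For Triple_KO against WT at 0 h (8528 genes) it recovered 52%, 86%, 100% and 98% at these folds, and 19 of the 201 genes called were unchanged, above the nominal rate. For the difference of decay values between Triple_KO and WT (8862 genes) it recovered 24%, 36%, 70% and 76%, with 0 unchanged among the 105 called (3 of 130 with edgeR). A list shifted by 0.5 was found by camera in each of these comparisons and an unchanged list was not.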

Results

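RNA levels were measured in 50 libraries of mouse embryonic stem cells: WT cells, cells labelled as a knockout of each of the 3 m6A readers Ythdf1, Ythdf2 and Ythdf3, and Triple_KO cells, labelled as a knockout of all 3. The series title asks whether the readers compensate for each other. For each genotype there were 4 libraries at 0 h, 2 at 4 h and 4 at 8 h of actinomycin D, from replicates A and B. Library totals ran from 796921 to 2341410 reads. Values are FPM, fold changes are log2 values of FPM + 1 with standard errors from limma (n = 2 replicates per genotype and time), and adjusted p-values are limma's unless camera is named. The largest rises and falls named for each comparison had the same sign in both replicates. Ubb-ps, Zfp951, Edem1 and Obi1 were named after their values were seen. Replicates A and B of a genotype differed no more than duplicate libraries of one replicate did: chi-square per degree of freedom had a median of 1.38 over 40 A against B pairs and 1.41 over 20 duplicate pairs, and in 0 pairs of either kind was the test's p above 0.05. The p-values thus measure a spread between samples that may be technical.

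The targeted genes were still read in the knockouts. Ythdf1, on chromosome 2 (180904377 to 180920936), had 56.9 ± 5.92 FPM in Ythdf1_KO at 0 h against 57.2 ± 8.05 in WT (SD, n = 4 libraries), and 42.5 ± 3.78 in Triple_KO. Ythdf2, on chromosome 4 (132184916 to 132212256), had 33.1 ± 4.20 FPM in Ythdf2_KO, 51.5 ± 7.69 in WT and 86.2 ± 11.4 in Triple_KO. Ythdf3, on chromosome 3 (16183148 to 16217037), was listed only by a noncoding transcript and had 23.8 ± 3.59 FPM in Ythdf3_KO, 23.2 ± 7.98 in WT and 21.5 ± 5.23 in Triple_KO. At 8 h the targeted gene had 16.6 ± 5.53 FPM (Ythdf1 in Ythdf1_KO), 8.36 ± 1.47 (Ythdf2 in Ythdf2_KO) and 9.69 ± 2.85 (Ythdf3 in Ythdf3_KO), against 11.7 ± 5.95, 10.8 ± 4.25 and 8.78 ± 2.36 in WT, and in Triple_KO it had 22.5 ± 3.64, 45.3 ± 6.95 and 18.5 ± 5.98. At 4 h (n = 2) the values were 33.5 ± 11.2, 19.2 ± 0.947 and 19.2 ± 6.66 in the single knockouts, 14.1 ± 0.416, 14.5 ± 0.192 and 14.1 ± 0.756 in WT, and 33.9 ± 7.00, 66.8 ± 1.00 and 24.6 ± 1.53 in Triple_KO. Reads from the 3′ end can lie outside the edited part of a gene, so these values check neither the knockouts nor the labels.

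**Figure D1:**
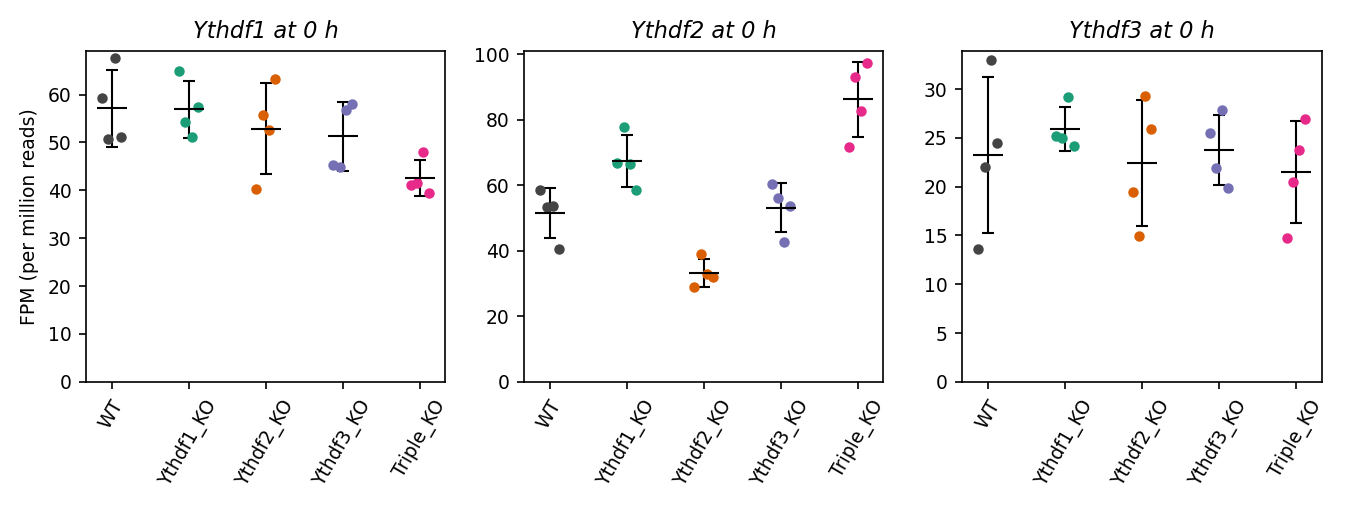
FPM of Ythdf1, Ythdf2 and Ythdf3 at 0 h (y axis) in each genotype (x axis), with 1 point per library, the mean as a bar and the SD as error bars (n = 4 libraries). Ythdf2 had 33.1 FPM in Ythdf2_KO and 86.2 FPM in Triple_KO, against 51.5 FPM in WT.

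The share of each library in the listed genes fell with time in actinomycin D in all genotypes except at 4 h in Triple_KO, and it fell least in Triple_KO. At 0 h it was 43.3 ± 0.654% in WT and 43.4 to 44.3% in the knockouts (means, n = 4 libraries). At 8 h it was 33.2 ± 0.266% in WT, 33.4 ± 1.07% in Ythdf1_KO, 30.5 ± 0.846% in Ythdf2_KO, 30.6 ± 0.417% in Ythdf3_KO and 41.1 ± 1.48% in Triple_KO. At 4 h Triple_KO had 45.1 ± 0.543% and WT 40.3 ± 0.770% (n = 2). In two-sided exact permutation tests of 4 libraries against 4 at 8 h, Ythdf2_KO, Ythdf3_KO and Triple_KO each differed from WT with p = 0.0286, the smallest these tests can give. Adjusted over the 8 comparisons p was 0.0762, which does not pass, and duplicate libraries are not independent.

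**Figure D2:**
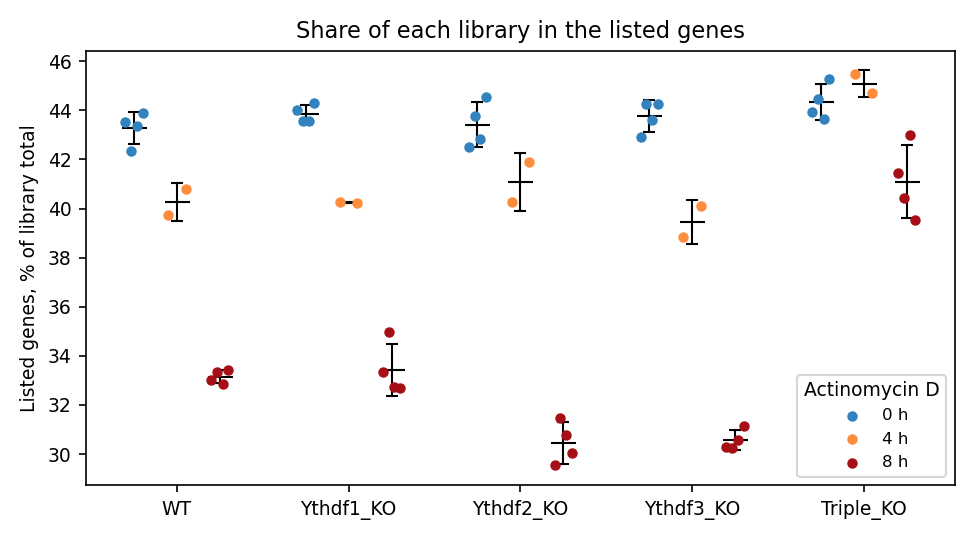
Share of each library's total in the listed genes, in percent (y axis), by genotype (x axis) at 0, 4 and 8 h, with 1 point per library, the mean as a bar and the SD as error bars. At 8 h Triple_KO lies at 41.1% and the other genotypes between 30.5% and 33.4%.

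After 8 h without transcription, WT cells had lost most regulators of pluripotency relative to the library total, while transcripts of ribosomal proteins and the respiratory chain stood above the median gene. Esrrb, a naive pluripotency factor, changed by -2.55 ± 0.11 (adjusted p = 2.56e-29) and Klf2, another, by -3.25 ± 0.16 (adjusted p = 1.20e-26). Among the largest falls were Dyrk3, a kinase (-3.99 ± 0.29), Trmt10c, a subunit of mitochondrial RNase P (-3.71 ± 0.51), Dnajb1, a heat shock cochaperone (-3.67 ± 0.39), and Socs3, a feedback inhibitor of JAK-STAT signalling (-3.54 ± 0.45). Mroh8, N4bp3, Med4 and Zfp459 fell likewise (-3.83 to -3.56), with adjusted p at most 3.05e-08 over these genes. The nuclear noncoding RNA Malat1 rose by 2.98 ± 0.15 and Tmem38b, an ion channel of the endoplasmic reticulum, by 3.48 ± 0.36. S100a4, Axl, Rpph1, Igf2, Acta2, Ift22, Qsox1 and Cd44 rose by 0.96 to 1.39 (adjusted p at most 0.0269). The readers fell too: Ythdf1 by -2.30 ± 0.23, Ythdf2 by -2.23 ± 0.23 and Ythdf3 by -1.28 ± 0.29 (adjusted p at most 1.93e-04).

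In this WT time course 20 of the 31 lists were called, and the 8 with the smallest p follow, with medians relative to that of all genes. Of 81 cytosolic ribosomal proteins measured, 19 rose, 9 fell and 24 changed adjusted over the list alone (median 0.82, camera adjusted p = 3.84e-19), among them Rplp0 (0.45 ± 0.04) and Rplp1 (0.36 ± 0.04). Nuclear genes of oxidative phosphorylation stood higher as well (15 rose and 13 fell of 75, 21 adjusted over the list alone, median 0.83, camera adjusted p = 5.45e-14), although their unshifted median was 0.02 and their mean -0.02; Cox6b1 rose by 0.31 ± 0.07 and Uqcrfs1 changed by -0.56 ± 0.13. Fibroblast feeder markers rose in 9 and fell in 2 of 25 genes (11 adjusted over the list alone, median 1.33, camera adjusted p = 1.62e-12), with Acta2, smooth muscle actin, at 1.01 ± 0.11 and Ccn1, a short-lived matrix protein transcript, at -3.44 ± 0.35. Short-lived regulators fell in 46 of 47 (46 adjusted over the list alone, median -1.74, camera adjusted p = 3.56e-10), as for the kinase Pim3 (-3.36 ± 0.24) and the survival factor Mcl1 (-2.62 ± 0.20). Transcripts of a list, drawn from memory, of m6A-marked transcripts in these cells fell in 47 of 51 (47 adjusted over the list alone, median -1.23, camera adjusted p = 3.42e-14). Naive pluripotency genes fell in 28 and rose in 1 of 32 (29 adjusted over the list alone, median -0.70, camera adjusted p = 2.82e-11). Core pluripotency genes fell in 17 and rose in 1 of 21 (18 adjusted over the list alone, median -1.13, camera adjusted p = 2.46e-09), including Sall4 (-2.07 ± 0.13) and L1td1 (-1.38 ± 0.09). Cell cycle genes fell in 33 of 37 (34 adjusted over the list alone, median -0.19, camera adjusted p = 9.87e-07), including the replication licensing factor Cdt1 (-3.00 ± 0.22) and the mitotic kinase Plk1 (-3.25 ± 0.27). All 8 held with an estimated correlation.

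Of the 9078 genes tested, 5164 changed over 8 h in WT: 157 rose and 5007 fell, and the median of all genes was -0.81. Median scaling moved that median by 0.59 and gave 1410 higher and 2328 lower genes, TMM scaling moved it by 0.66 and gave 1597 and 2114, and under both Uqcrfs1 turned to a higher value and the cell cycle list and Ythdf3 were not called. At 4 h the count was 2802, Axl stood at -0.24 and S100a4, Rpph1, Igf2, Ift22, Cd44, Ythdf3 and Uqcrfs1 did not pass. Leaving out replicate A ended the calls of Axl, Rpph1, Ift22, Qsox1 and Cd44, and leaving out replicate B those of Cd44, Ythdf3 and Cox6b1. Genes with an internal exon of at least 400 nt, where m6A is often found, had a median of -1.24 against -0.71 for the others (camera adjusted p = 0.00154), and genes with few exon junctions -1.35 against -0.71 (camera adjusted p = 0.00154), a difference that turned to 0.12 without the filter on low values (camera adjusted p = 0.298). For genes with a long 3′ UTR it was -1.09 against -0.75 (camera adjusted p = 0.25), and this list was called under both scalings.

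At 0 h, Ythdf1_KO cells had higher levels of Khdc3, an oocyte and stem cell protein of genome stability (1.92 ± 0.31, adjusted p = 1.57e-06), and of the imprinted growth factor Igf2 (1.70 ± 0.22, adjusted p = 1.96e-10). Tmem37, Slc16a6, a monocarboxylate transporter, and Wdr41 rose by 1.35 ± 0.23, 1.34 ± 0.28 and 1.20 ± 0.30 (adjusted p at most 0.00711). Kbtbd11 was lower (-1.75 ± 0.27, adjusted p = 2.10e-07), as were Pcca, a subunit of propionyl-CoA carboxylase (-1.31 ± 0.29), the small RNA Rn4.5s (-1.03 ± 0.24) and the innate immune receptor Nod1 (-0.98 ± 0.28), with adjusted p at most 0.0236. Trophectoderm markers were the 1 list called: 3 of 12 rose and 5 changed adjusted over the list alone (median 0.40, camera adjusted p = 0.00399, but adjusted p = 0.309 with an estimated correlation), with the keratins Krt18 at 0.91 ± 0.13 and Krt8 at 0.44 ± 0.10. Readers did not pass the test: Ythdf1 -0.0021 ± 0.13, Ythdf2 0.39 ± 0.12 and Ythdf3 0.21 ± 0.19 (adjusted p = 0.998, 0.0574 and 0.684).

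Of 8697 genes tested, 228 changed in Ythdf1_KO, 150 higher and 78 lower. Without Ythdf1_KO replicate B the count was 105, without the filter 57, with a fit on all times 20. Calls ended for Pcca and Rn4.5s without Ythdf1_KO replicate B or WT replicate B, for Slc16a6, Wdr41 and Nod1 without Ythdf1_KO replicate A or WT replicate A, for Nod1 without WT replicate B, for Krt8 without WT replicate A and for the trophectoderm list without Ythdf1_KO replicate A, while Ythdf2 passed as higher without WT replicate A. Genes of chromosome 13 stood 0.17 above the median of all genes in each of the replicates (292 genes), and 22 of the 150 higher genes lay there (Fisher's exact test against genes elsewhere, p = 4.64e-09).

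**Figure D3:**
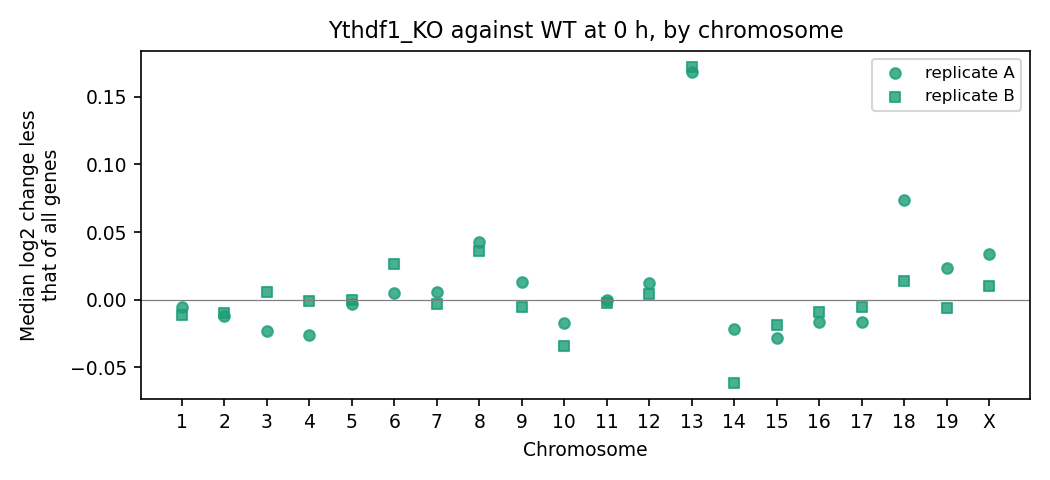
Median log2 change of the tested genes of each chromosome (x axis) in Ythdf1_KO against WT at 0 h, less the median of all genes (y axis), with 1 point per replicate. Chromosome 13 lies at 0.17 in both replicates.

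In Ythdf2_KO cells glycolysis genes were higher at 0 h and fibroblast feeder markers and p53 targets lower. Igf2 (1.90 ± 0.22) and Dppa3, a maternal factor of naive cells (1.87 ± 0.25), had the largest rises, followed by Slc16a6 (1.68 ± 0.28), the mitophagy receptor Bnip3 (1.58 ± 0.25) and the Wnt target Axin2 (1.57 ± 0.32), with adjusted p at most 7.81e-05. The imprinted genes Plagl1 (-2.42 ± 0.33) and Grb10 (-1.97 ± 0.14) fell, as did the noncoding RNA Dancr (-1.94 ± 0.18), Snora44 (-1.68 ± 0.32) and Snora26 (-1.68 ± 0.27), with adjusted p at most 2.48e-05. Snora26 lies inside Dancr on chromosome 5, so their reads are not separable. Ythdf2 itself was lower (-0.62 ± 0.12, adjusted p = 5.72e-05), and Ythdf1 (-0.12 ± 0.13, adjusted p = 0.677) and Ythdf3 (-0.03 ± 0.19, adjusted p = 0.953) did not pass.

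In Ythdf2_KO 10 lists were called at 0 h. Glycolysis genes rose in 14 of 28 (15 adjusted over the list alone, median 0.27, camera adjusted p = 5.29e-17), led by Ldha, lactate dehydrogenase (0.53 ± 0.05), and Tpi1 (0.45 ± 0.06). Feeder markers fell in 6 of 22 (7 adjusted over the list alone, median -0.48, camera adjusted p = 1.98e-06), among them S100a6 (-0.79 ± 0.08). Targets of p53 fell in 10 and rose in 1 of 33 (15 adjusted over the list alone, median -0.31, camera adjusted p = 1.08e-04). Among them were Ccng1 (-0.55 ± 0.09) and Phlda3 (-0.45 ± 0.08). These 3 held with an estimated correlation and the other 5 did not. Ribosomal proteins rose in 9 and fell in 2 of 80 (17 adjusted over the list alone, median 0.06, camera adjusted p = 1.98e-06, adjusted p = 0.317 with an estimated correlation). Among them were Rpl41 (0.21 ± 0.03) and Rps20 (0.15 ± 0.02). Integrated stress response genes rose in 7 and fell in 1 of 32 (12 adjusted over the list alone, median 0.15, camera adjusted p = 1.75e-04, adjusted p = 0.102 with an estimated correlation), including the mitochondrial enzyme Pck2 (0.74 ± 0.10) and asparagine synthetase, Asns (0.31 ± 0.05). The m6A list fell in 10 of 50 (11 adjusted over the list alone, median -0.16, camera adjusted p = 4.88e-04, adjusted p = 0.081 with an estimated correlation), including Klf5 (-0.67 ± 0.08) and Tbx3 (-0.44 ± 0.08). FGF and ERK feedback genes fell in 3 of 12 (4 adjusted over the list alone, median -0.22, camera adjusted p = 0.00334, adjusted p = 0.102 with an estimated correlation). Among them were Phlda1 (-1.30 ± 0.20) and Spry2 (-0.86 ± 0.13). DNA methylation and chromatin regulators fell in 6 and rose in 2 of 33 (8 adjusted over the list alone, median -0.14, camera adjusted p = 0.00667, adjusted p = 0.158 with an estimated correlation), with Dnmt3l, a cofactor of de novo methylation, at -1.04 ± 0.08 and Uhrf1 at 0.26 ± 0.06.

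In Ythdf2_KO 713 genes changed, 346 higher and 367 lower, or 447 and 286 with TMM scaling. The count was 372 and 349 without Ythdf2_KO replicate A and B, the latter of which ended the call of Uhrf1, 312 without the filter and 141 with a fit on all times.

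Ythdf3_KO cells also had higher glycolysis and stress response genes at 0 h, and lower endoderm, feeder and p53 genes. Stmn2, a neuronal regulator of microtubules, rose by 1.28 ± 0.10 (adjusted p = 5.32e-26) and Rbfa, a mitochondrial ribosome factor, by 1.20 ± 0.14 (adjusted p = 1.21e-12). Dis3l2, an exonuclease of uridylated RNA (1.23 ± 0.29), Bnip3 (1.14 ± 0.25) and Ndufaf3 (1.03 ± 0.23) rose too, with adjusted p at most 0.00251. The splicing regulator Mbnl2 (-1.24 ± 0.23), the formin Inf2 (-1.24 ± 0.26), the small heat shock protein Cryab (-1.21 ± 0.23), Mycbp2 (-1.14 ± 0.28) and the basement membrane collagen Col4a1 (-1.12 ± 0.25) fell, with adjusted p at most 0.00457. No reader passed: Ythdf1 -0.15 ± 0.13, Ythdf2 0.05 ± 0.12 and Ythdf3 0.09 ± 0.19 (adjusted p = 0.599, 0.911 and 0.887).

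Of the 11 lists called in Ythdf3_KO at 0 h, 5 of the 8 described held with an estimated correlation. Glycolysis genes rose in 12 of 28 (15 adjusted over the list alone, median 0.19, camera adjusted p = 3.81e-15). Among them were Ldha (0.38 ± 0.05) and Aldoa (0.22 ± 0.03). Primitive and definitive endoderm markers fell in 7 and rose in 1 of 12 (10 adjusted over the list alone, median -0.52, camera adjusted p = 1.82e-10), with Krt8 at -0.96 ± 0.10. Stress response genes rose in 8 of 32 (14 adjusted over the list alone, median 0.18, camera adjusted p = 2.71e-10). Among them were Pck2 (0.66 ± 0.10) and Asns (0.33 ± 0.05). Feeder markers fell in 4 of 22 (7 adjusted over the list alone, median -0.34, camera adjusted p = 6.61e-08). Among them were S100a6 (-0.76 ± 0.08) and Ccn2 (-0.55 ± 0.10). Targets of p53 fell in 5 of 33 (6 adjusted over the list alone, median -0.20, camera adjusted p = 2.36e-05). Among them were Perp (-0.87 ± 0.13) and Phlda3 (-0.45 ± 0.08). Ribosomal proteins rose in 15 and fell in 1 of 80 (31 adjusted over the list alone, median 0.10, camera adjusted p = 1.22e-15, adjusted p = 0.159 with an estimated correlation). Among them were Rps20 (0.17 ± 0.02) and Rps26 (0.33 ± 0.05). Trophectoderm markers, which share Krt8 with the endoderm list, fell in 3 of 12 (6 adjusted over the list alone, median -0.22, camera adjusted p = 6.04e-04, adjusted p = 0.0523 with an estimated correlation), with Lgals3 at -0.65 ± 0.10. Oxidative phosphorylation genes rose in 5 of 75 (5 adjusted over the list alone, median 0.06, camera adjusted p = 0.00246, adjusted p = 0.335 with an estimated correlation). Among them were Uqcrq (0.29 ± 0.06) and Uqcr10 (0.20 ± 0.05).

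In Ythdf3_KO 388 genes changed, 215 higher and 173 lower. The count was 209 without WT replicate A, 173 and 180 without Ythdf3_KO replicate A and B, 102 without the filter and 68 with a fit on all times. Calls ended for Dis3l2, Uqcr10 and the oxidative phosphorylation list without WT replicate A, for Mycbp2 without WT replicate B or Ythdf3_KO replicate A, for Uqcr10 without the latter, and for Dis3l2, Bnip3, Ndufaf3, Col4a1, Ccn2, Uqcrq and the oxidative phosphorylation list without Ythdf3_KO replicate B.

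Triple_KO cells at 0 h had higher germline and fibroblast marker genes than WT and lower glycolysis and core pluripotency genes, each called as a list. A 2-cell-like list, with 6 genes measured, was also called as higher. None of these calls held with an estimated correlation (adjusted p = 0.0551 to 0.153). The rises were led by Steap3, a metalloreductase (2.95 ± 0.46), the neurofilament gene Nefm (2.73 ± 0.47), Bhmt, a homocysteine methyltransferase (2.65 ± 0.40), Dppa3 (2.55 ± 0.25) and Rhox5, an X-linked homeobox gene (2.49 ± 0.22). Tfap2c, a transcription factor of trophectoderm and germ cells (2.39 ± 0.23), and Fkbp6, a meiosis gene (2.35 ± 0.46), rose as well, as did Mir147, Rab3il1 and Tmem37 (2.33 to 2.43), with adjusted p at most 1.25e-05 over these 10. The largest falls were those of Dancr (-2.52 ± 0.18), Aire (-2.17 ± 0.35), which overlaps Dnmt3l on chromosome 10, Rn4.5s (-1.96 ± 0.24), Snora26 inside Dancr (-1.93 ± 0.27) and Islr2 (-1.90 ± 0.18). Xaf1, a binding partner of XIAP, the calcium pump Atp2a3, Gpa33, Septin1 and Kbtbd11 fell likewise (-1.86 to -1.71), with adjusted p at most 4.44e-08 over these 10. Ythdf2 was higher (0.73 ± 0.12, adjusted p = 1.72e-07), Ythdf1 lower (-0.41 ± 0.13, adjusted p = 0.00923), and Ythdf3 did not pass (-0.08 ± 0.19, adjusted p = 0.821).

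None of the 8 lists described of the 14 called in Triple_KO at 0 h held with an estimated correlation. Germline genes rose in 7 of 10 (7 adjusted over the list alone, median 1.19, camera adjusted p = 1.27e-04, adjusted p = 0.0551 with an estimated correlation). Genes of the 2-cell-like state rose in 4 of 6 (5 adjusted over the list alone, median 1.34, camera adjusted p = 0.00198, adjusted p = 0.0804 with an estimated correlation). Among them were Eif1a (0.69 ± 0.09) and Pramel7 (2.34 ± 0.48). Fibroblast feeder markers rose in 11 of 22 (15 adjusted over the list alone, median 0.66, camera adjusted p = 1.82e-05, adjusted p = 0.0551 with an estimated correlation). Among them were Acta2 (0.83 ± 0.10) and Tagln (0.84 ± 0.12). Targets of p53 rose in 11 and fell in 1 of 33 (13 adjusted over the list alone, median 0.23, camera adjusted p = 0.00323, adjusted p = 0.0753 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.77 ± 0.10 and Mdm2 at 0.64 ± 0.10. Glycolysis genes fell in 15 and rose in 4 of 28 (20 adjusted over the list alone, median -0.29, camera adjusted p = 5.35e-07, adjusted p = 0.0551 with an estimated correlation), with pyruvate kinase, Pkm, at -0.38 ± 0.03 and Ldha at -0.57 ± 0.05. Ribosomal proteins fell in 19 and rose in 3 of 80 (27 adjusted over the list alone, median -0.07, camera adjusted p = 5.35e-07, adjusted p = 0.236 with an estimated correlation). Among them were Rpl22l1 (-0.96 ± 0.08) and Rpl8 (-0.28 ± 0.03). Core pluripotency genes fell in 8 and rose in 1 of 21 (9 adjusted over the list alone, median -0.12, camera adjusted p = 8.32e-05, adjusted p = 0.153 with an estimated correlation). Among them were Tdgf1 (-0.52 ± 0.05) and Dnmt3l (-0.72 ± 0.08). Naive pluripotency genes went both ways (12 fell and 5 rose of 32, 19 adjusted over the list alone, median -0.12, camera adjusted p = 6.57e-04, adjusted p = 0.0551 with an estimated correlation). Among them were Klf5 (-1.24 ± 0.08) and Fbxo15 (1.28 ± 0.11).

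**Figure D4:**
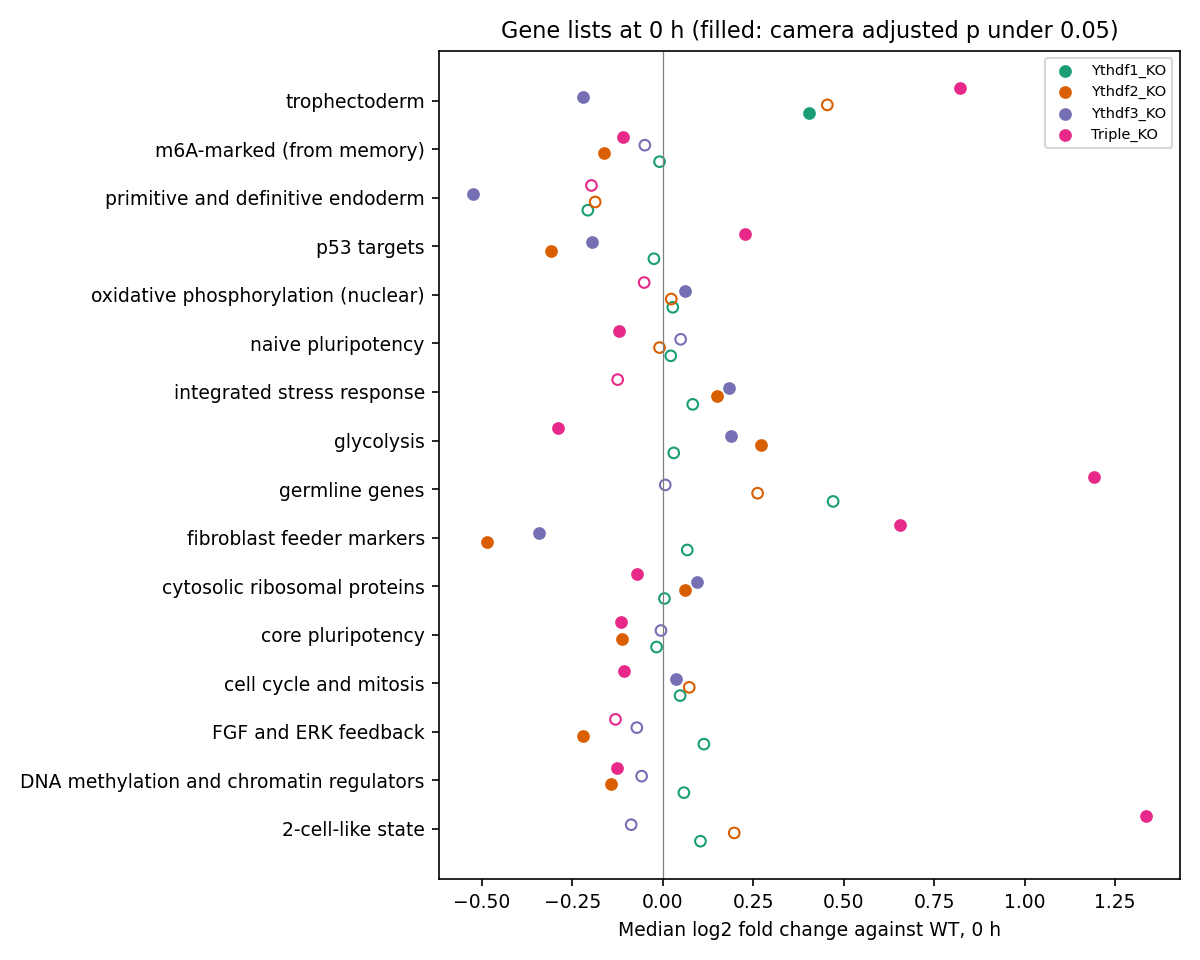
Median log2 fold change against WT at 0 h (x axis) of the described gene lists (y axis), with 1 point per knockout and filled points where camera's adjusted p passed. Glycolysis lies at 0.27 in Ythdf2_KO and -0.29 in Triple_KO, and fibroblast feeder markers at -0.48 and 0.66.

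In Triple_KO 1906 of 8697 genes changed, 1241 higher and 665 lower, and median scaling gave 933 and 906, TMM scaling 972 and 863. The count was 1129 and 1166 without Triple_KO replicate A and B and 559 with a fit on all times, and the call of Ythdf1 ended without WT replicate B or Triple_KO replicate A.

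Against the mean of the single knockouts, Triple_KO cells had higher fibroblast feeder markers and p53 targets at 0 h and lower glycolysis, stress response and naive pluripotency genes, each called as a list. Fkbp6 (2.57 ± 0.38), Bhmt (2.42 ± 0.32), Nefm (2.38 ± 0.38), Pramel6 (2.36 ± 0.34), Steap3 (2.15 ± 0.38) and Ly6a, a surface antigen (2.06 ± 0.29), were higher, and so were Rhox5, Sord, Rab3il1 and the germ cell helicase Ddx4 (1.73 to 2.04), with adjusted p at most 5.65e-06 over these 10. Pla2g1b, a secreted phospholipase (-1.88 ± 0.16), Dancr (-1.57 ± 0.15), Rn4.5s (-1.56 ± 0.19) and Septin1 (-1.46 ± 0.13) were lower, and so were Mid1ip1, Atp2a3, Gpa33, Xaf1, Fblim1 and Calca (-1.39 to -1.17), with adjusted p at most 7.22e-07. Ythdf2 was higher (0.80 ± 0.10, adjusted p = 1.76e-12) and Ythdf1 lower (-0.32 ± 0.10, adjusted p = 0.013), while Ythdf3 did not pass (-0.17 ± 0.15, adjusted p = 0.488).

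Against the single knockouts 15 lists were called at 0 h. Fibroblast feeder markers were higher in 16 of 22 (21 adjusted over the list alone, median 0.87, camera adjusted p = 7.97e-15). Among them were Acta2 (0.86 ± 0.08) and Ccn2 (0.77 ± 0.08). Targets of p53 were higher in 21 and lower in 1 of 33 (24 adjusted over the list alone, median 0.45, camera adjusted p = 4.99e-10). Among them were Phlda3 (0.79 ± 0.07) and Mdm2 (0.73 ± 0.08). Glycolysis genes were lower in 16 and higher in 3 of 28 (21 adjusted over the list alone, median -0.41, camera adjusted p = 2.80e-24). Among them were Ldha (-0.86 ± 0.04) and Pkm (-0.48 ± 0.02). Stress response genes were lower in 14 and higher in 3 of 32 (18 adjusted over the list alone, median -0.20, camera adjusted p = 9.96e-08), with the arginine transporter Slc7a3 at -0.84 ± 0.09 and Shmt2 at -0.52 ± 0.06. Naive pluripotency genes were lower in 15 and higher in 3 of 32 (22 adjusted over the list alone, median -0.19, camera adjusted p = 1.17e-06). Among them were Dppa5a (-0.43 ± 0.03) and Klf5 (-0.62 ± 0.07). These 5 held with an estimated correlation and the other 3 did not. Ribosomal proteins were lower in 51 and higher in 1 of 80 (56 adjusted over the list alone, median -0.13, camera adjusted p = 9.28e-23, adjusted p = 0.0643 with an estimated correlation). Among them were Rpl22l1 (-0.90 ± 0.06) and Rpl8 (-0.20 ± 0.02). Cell cycle genes were lower in 12 of 37 (15 adjusted over the list alone, median -0.13, camera adjusted p = 1.13e-04, adjusted p = 0.0632 with an estimated correlation). Among them were Uhrf1 (-0.33 ± 0.05) and Pcna (-0.52 ± 0.08). Oxidative phosphorylation genes were lower in 17 and higher in 4 of 75 (23 adjusted over the list alone, median -0.06, camera adjusted p = 1.94e-04, adjusted p = 0.193 with an estimated correlation). Among them were Ndufa4 (-0.38 ± 0.05) and Ndufs6 (-0.28 ± 0.05).

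In this comparison 2003 genes changed, 1341 higher and 662 lower, and median scaling gave 947 and 1037, TMM scaling 965 and 1012. The count was 1042 and 1061 without Triple_KO replicate A and B and 633 with a fit on all times, and the call of Ythdf1 ended without either Triple_KO replicate or without replicate B of Ythdf2_KO or Ythdf3_KO.

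The differences of the knockout cells from WT at 0 h resembled each other in part. Across 8697 genes, which are not independent replicates, Pearson correlations of fold changes against WT ran from 0.41 (Ythdf3_KO and Triple_KO) to 0.66 (Ythdf2_KO and Ythdf3_KO) over the 6 pairs, beside 0.50 for simulated unchanged groups that share the WT libraries. With the WT replicates split between the pair they ran from 0.12 to 0.28. The covariance less the simulated one ran from 0.0249 to 0.0593. Ythdf2_KO and Triple_KO shared 207 higher genes and 169 lower genes, beside 49.4 and 28.1 for independent lists and 0 and 0 in 100 simulations of unchanged groups that share the WT libraries, and 49 genes went opposite ways. With the WT replicates split, where fewer genes were called in each, they shared 115 and 86 (40 opposite), or 110 and 80 (31 opposite) with WT replicates A and B exchanged. For Ythdf3_KO and Triple_KO these numbers were 106 and 69 (54 opposite), beside 30.7 and 13.2 for independent lists, and 51 and 34 (48 opposite) or 38 and 26 (31 opposite) with the split. The value for independent lists leaves out the shared WT libraries. The simulated value leaves out the effects, and with adjusted p-values it lies near 0 by construction, so neither is a reference for an overlap of real effects. For decay values the correlations ran from 0.47 to 0.54 beside a simulated 0.50, and the covariance less the simulated one from -0.0196 to 0.000276.

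In Ythdf1_KO the loss of transcripts over 8 h differed from WT in 4 genes, all with a smaller fall. Slc2a1, a glucose transporter, had a difference of decay values of 0.85 ± 0.14 (adjusted p = 5.98e-04), the chaperone Hspa8 of 0.38 ± 0.08 (adjusted p = 0.0136) and the ubiquitin gene Ubb of 0.56 ± 0.12 (adjusted p = 0.0183). Ubb-ps, a pseudogene with nearly the same values as Ubb, is uncertain (0.56 ± 0.12, adjusted p = 0.0183). The readers had 0.54 ± 0.33 (Ythdf1), -0.38 ± 0.32 (Ythdf2) and -0.27 ± 0.42 (Ythdf3), each with adjusted p = 0.991. In 3 lists called by camera 0 members passed limma's test, over all genes or adjusted over the list alone: ribosomal proteins (81 measured, median -0.06, camera adjusted p = 6.87e-05, adjusted p = 0.488 with an estimated correlation), oxidative phosphorylation genes (75 measured, median -0.09, camera adjusted p = 0.00193, adjusted p = 0.424 with an estimated correlation) and feeder markers (25 measured, median 0.32, camera adjusted p = 0.0118, adjusted p = 0.0777 with an estimated correlation). Of their members, Rplp0 had -0.19 ± 0.05, Rpl41 -0.15 ± 0.05, Sdha -0.59 ± 0.17, Ndufa7 -0.38 ± 0.12, Loxl1 1.24 ± 0.66 and S100a6 0.21 ± 0.13, none past the test. At an unadjusted p under 0.05 there were 470 genes, and edgeR on recovered reads called 4. Median and TMM scaling each called 10 genes, 4 higher and 6 lower, Rplp0 and Rpl41 among the lower. The count was 1 without WT replicate A or B, 2 without Ythdf1_KO replicate A and 0 without replicate B (465 at an unadjusted p under 0.05), at 4 h it was 0 (490 unadjusted), and there Slc2a1 and the feeder list had the opposite sign. Calls ended for Slc2a1 without WT replicate A or Ythdf1_KO replicate B, for Hspa8 without WT replicate B or either Ythdf1_KO replicate, and for Ubb and Ubb-ps without any 1 of the 4. All 3 lists lost theirs without WT replicate A, the first 2 also without Ythdf1_KO replicate B and the feeder list without Ythdf1_KO replicate A.

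In Ythdf2_KO 16 genes had a lower decay value than in WT and 0 a higher one (limma; 647 at an unadjusted p under 0.05; 32 and 0 with edgeR). Tmem38b, which rose in WT, had a difference of -2.22 ± 0.51, the integrin Itgb5 of -1.49 ± 0.35, Sra1 of -1.17 ± 0.27, the myosin Myo1c of -1.01 ± 0.22 and Naca, a nascent chain binding protein, of -0.50 ± 0.11 (adjusted p = 0.0482 for each). The readers did not pass: Ythdf1 -0.14 ± 0.33, Ythdf2 0.35 ± 0.32 and Ythdf3 0.29 ± 0.42 (adjusted p = 0.981, 0.929 and 0.968). The median of all genes was -0.13, which median scaling moved by 0.12 and TMM scaling by 0.11, and both left 0 genes called (449 and 442 at an unadjusted p under 0.05; 32 with edgeR on unscaled reads). The count was 0 without WT replicate A, WT replicate B or Ythdf2_KO replicate A (487, 634 and 504 unadjusted) and 2 without Ythdf2_KO replicate B, so that no named call held in each of these, and 55 with libraries kept separate.

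For this difference 9 lists were called, and none of the 8 described held with an estimated correlation. Medians are relative to that of all genes. Protein synthesis factors were lower in 2 of 37 (5 adjusted over the list alone, camera adjusted p = 5.36e-04, adjusted p = 0.085 with an estimated correlation), with Naca and Npm1 (-0.21 ± 0.05) past the test, although the list's median was 0.01. Ribosomal proteins were lower in 1 of 81, Rpl41 (-0.22 ± 0.05), with 2 adjusted over the list alone. Yet their median was 0.06 (camera adjusted p = 0.0294, 0.557 with an estimated correlation). Both scalings turned this call to higher and ended that of protein synthesis. Rpl4 had -0.17 ± 0.05. Glycolysis genes were lower in 1 of 28, Pkm (-0.22 ± 0.05), with 2 adjusted over the list alone (median -0.0078, camera adjusted p = 0.0294, adjusted p = 0.196 with an estimated correlation), and Eno1, which shares its values with a near-identical gene, had -0.28 ± 0.08. In the other 5 lists 0 members passed limma's test over all genes, and the counts adjusted over the list alone were 3 of 37 cell cycle genes, 2 of 25 feeder markers, 1 of 47 short-lived regulators, 0 of 51 transcripts of the m6A list and 0 of 12 FGF and ERK feedback genes. Their medians were -0.15, -0.35, 0.25, 0.22 and 0.39 (camera adjusted p = 0.0142, 0.0176, 0.0294, 0.0294 and 0.0294). The adjusted p = 0.0505, 0.0505, 0.0812, 0.0812 and 0.0812 with an estimated correlation. Members with the smallest p were Ccnb1 (-0.79 ± 0.25), Mcm6 (-0.48 ± 0.15), S100a6 (-0.48 ± 0.13), Acta2 (-0.51 ± 0.15), Sgk1 (-1.30 ± 0.36), Dusp1 (-1.90 ± 0.73), Eed (-0.70 ± 0.22), Setd1b (1.87 ± 0.72), Myc (1.93 ± 0.81) and Phlda1 (1.26 ± 0.54), none past the test. Each of these 8 calls but that of the protein synthesis list also ended in at least 2 of the fits that left out a replicate, and that one without Ythdf2_KO replicate B.

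In Ythdf3_KO ribosomal protein transcripts had lower decay values than in WT (list median 0.011). They were lower in 14 of 81 (54 adjusted over the list alone, median -0.27, camera adjusted p = 4.64e-60). Rps20 and Rplp1 had -0.35 ± 0.05 (adjusted p = 1.76e-06 and 2.24e-05). Medians are unshifted, beside -0.077 for all genes. Cacybp (-0.72 ± 0.17), the cell cycle kinase Cdk4 (-0.48 ± 0.10), Get3 (-0.39 ± 0.10), Rpl19 (-0.38 ± 0.08) and the Rps23 retrogene Rps23rg1 (-0.36 ± 0.08) were the largest differences, with adjusted p at most 0.0434. Oxidative phosphorylation genes (0 of 75 over all genes, 11 adjusted over the list alone, median -0.23, camera adjusted p = 3.02e-12), with Atp5b at -0.25 ± 0.07 and Cox7b at -0.36 ± 0.10, and protein synthesis factors (0 of 37, 7 adjusted over the list alone, median -0.13, camera adjusted p = 1.38e-06), with Eif3c at -0.45 ± 0.13 and Eef1b2 at -0.22 ± 0.06, were lower as lists. These 3 held with an estimated correlation. Glycolysis genes (1 lower of 28, Pkm at -0.22 ± 0.05, 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.00409, adjusted p = 0.0912 with an estimated correlation) and unfolded protein response genes (0 of 29, 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.0195, adjusted p = 0.121 with an estimated correlation) did not. Short-lived regulators stood higher as a list (0 of 47, 0 adjusted over the list alone, median 0.21, camera adjusted p = 0.0205, adjusted p = 0.0545 with an estimated correlation). Eno1 (-0.26 ± 0.08), Pdia3 (-0.33 ± 0.10), Hspd1 (-0.27 ± 0.10), Sgk1 (-1.21 ± 0.36) and Ccn1 (1.01 ± 0.49) did not pass, nor did Ythdf1 (0.03 ± 0.33), Ythdf2 (-0.03 ± 0.32) or Ythdf3 (0.03 ± 0.42), with adjusted p = 0.996, 0.996 and 0.997.

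The count in Ythdf3_KO was 30, all lower, and 74 with edgeR, 59 with libraries kept separate, 14 with median and 4 with TMM scaling, and 6, 14, 10 and 7 without WT replicate A, WT replicate B, Ythdf3_KO replicate A and Ythdf3_KO replicate B. Each of the named calls except those of Rps20 and Rplp1 ended without some replicate, as did those of the unfolded protein and short-lived lists without WT replicate A or Ythdf3_KO replicate A. Genes with a long 3′ UTR stood 0.09 above the others (camera adjusted p = 0.0450).

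In Triple_KO most transcripts fell less over 8 h than in WT. Esrrb had a difference of decay values of 1.42 ± 0.16 (adjusted p = 7.27e-10) and Sall4, a core pluripotency factor, of 1.28 ± 0.19 (adjusted p = 1.70e-06), beside a median of 0.37 over all genes. The largest differences were those of Lsm10, a U7 snRNP subunit (2.76 ± 0.58), the mitochondrial carrier Slc25a33 (2.41 ± 0.62), Pheta1 (2.37 ± 0.70), Ccdc71 (2.36 ± 0.53) and Arl6ip6 (2.31 ± 0.53). Rita1, Trp53rka, the arginine methyltransferase Prmt6 and Rpp25l had 2.21 to 2.29, with adjusted p at most 0.0232 over these genes. Tmem38b (-2.17 ± 0.51, adjusted p = 0.00291) and Zfp951 (-2.30 ± 0.76, adjusted p = 0.0495) were the 2 genes with a lower decay value, and the former rose in WT. Ythdf1 (1.40 ± 0.33, adjusted p = 0.00278) and Ythdf2 (1.31 ± 0.32, adjusted p = 0.00426) fell less, and Ythdf3 did not pass (1.04 ± 0.42, adjusted p = 0.122).

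For Triple_KO against WT 7 lists were called, given here with medians relative to that of all genes. Naive pluripotency genes were higher in 9 of 32 (17 adjusted over the list alone, median 0.21, camera adjusted p = 1.95e-05), with Mybl2 at 0.81 ± 0.14. Feeder markers were lower as a list, with 0 of 25 past limma's test (0 adjusted over the list alone, median -0.43, camera adjusted p = 1.76e-06), and Tagln at -0.45 ± 0.19. Germline genes were lower as a list (0 of 13, 0 adjusted over the list alone, median -0.56, camera adjusted p = 0.00259), Piwil2 at -1.80 ± 0.80 and Tuba3a at 1.16 ± 0.65. Ribosomal proteins were called as higher (33 of 81, 51 adjusted over the list alone, camera adjusted p = 2.86e-19), with Rpl23 at 0.49 ± 0.06 and Rpl4 at 0.38 ± 0.05, but their median was -0.10, and median scaling, TMM scaling and 4 h turned the call to lower. Protein synthesis factors were called as higher (15 of 37, 21 adjusted over the list alone, camera adjusted p = 2.25e-11), with Eef1b2 at 0.60 ± 0.06 and Eef1a1 at 0.33 ± 0.05, beside a median of -0.0058, and both scalings turned the call to lower. These 5 held with an estimated correlation. Oxidative phosphorylation genes were called as higher (9 of 75, 14 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.336 with an estimated correlation), with Uqcr10 at 0.47 ± 0.09 and Ndufb5 at 0.68 ± 0.15, beside a median of -0.14, and both scalings and 4 h turned the call to lower. Core pluripotency genes were higher in 4 of 21 (4 adjusted over the list alone, median 0.13, camera adjusted p = 0.0208, adjusted p = 0.104 with an estimated correlation), with L1td1 at 0.81 ± 0.12. The naive, germline and core pluripotency lists were not called under either scaling.

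Of 9078 genes, 657 had a changed decay value in Triple_KO, 655 higher and 2 lower. Median scaling moved the median of all genes by -0.33 and gave 160 genes, 98 higher and 62 lower, of which 99 were among the 657, and TMM scaling moved it by -0.33 and gave 152, 90 and 62. The count was 421, 355, 203 and 183 without WT replicate A, WT replicate B, Triple_KO replicate A and Triple_KO replicate B, 141 at 4 h, 183 with a straight line, 1154 with libraries kept separate and 1292 with edgeR. Without Triple_KO replicate A the calls of Lsm10, Slc25a33, Pheta1, Arl6ip6, Rita1, Trp53rka, Prmt6, Tmem38b, Ythdf1, Ythdf2, Zfp951 and the core list ended. Without Triple_KO replicate B those of Slc25a33, Pheta1, Ccdc71, Arl6ip6, Rita1, Trp53rka, Prmt6, Ythdf2, Zfp951 and the germline list did. Leaving out WT replicate A ended those of Pheta1, Rita1, Trp53rka, Tmem38b, Zfp951, Ndufb5 and the core list, and WT replicate B those of Slc25a33, Prmt6, Ythdf1, Ythdf2, Zfp951 and the oxidative phosphorylation list. The spread of decay values across genes was narrower in Triple_KO, by a mean of -0.14, or -0.20 with median or TMM scaling. Its SD was 0.73 and 0.72 against 0.84 to 0.91 in the other 8 replicates. The two-sided exact permutation p was 0.0222, the smallest possible (adjusted p = 0.0296 over 4 measures). A and B may not be independent. The gap between short-lived regulators and ribosomal proteins was -2.12 and -2.0 against -2.60 to -1.81 (exact permutation p = 0.356). Genes with long internal exons, few junctions or a long 3′ UTR stood 0.07, 0.18 and 0.09 above the others in the Triple_KO difference, and none passed (camera adjusted p = 0.393, 0.357 and 0.357); camera's direction was down for the first and the last, and the few-junction genes were called as higher under both scalings and at 4 h, but stood at -0.16 without the filter (camera adjusted p = 0.318). With a pseudocount of 5 FPM the long-exon value was -0.0036.

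**Figure D5:**
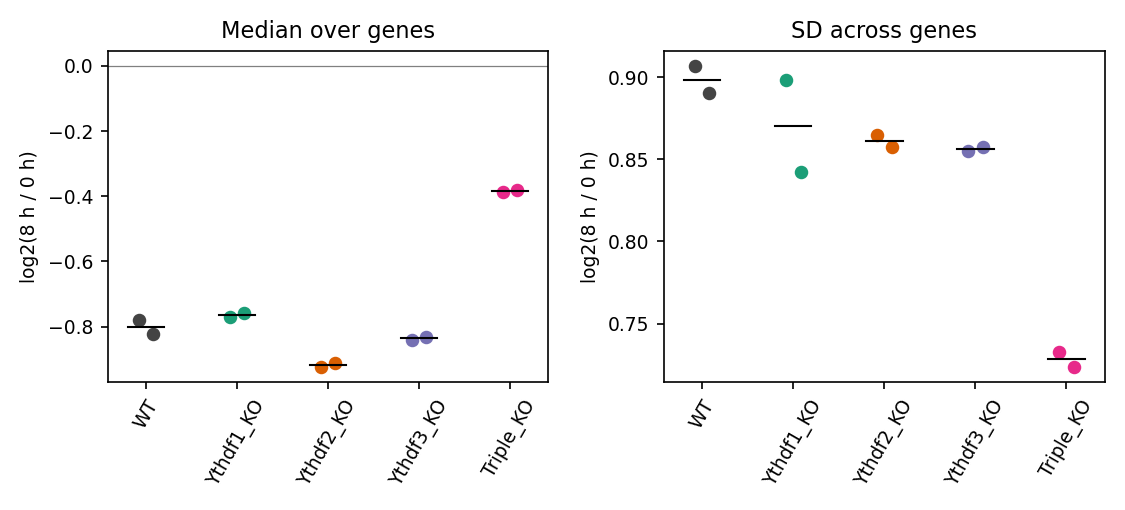
Median over 9078 genes (left panel) and SD across genes (right panel) of log2(8 h / 0 h) on the y axes, by genotype (x axes), with 1 point per replicate and the mean as a line. In Triple_KO the medians are -0.39 and -0.38 and the SD 0.73 and 0.72, against medians of -0.92 to -0.76 and an SD of 0.84 to 0.91 in the other genotypes.

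Most transcripts of Triple_KO also fell less than in the mean of the single knockouts. Commd5 (2.42 ± 0.32), Tigar, a fructose bisphosphatase and p53 target (2.07 ± 0.39), Rabif (2.05 ± 0.53), Sac3d1 (2.05 ± 0.30), the endosomal GTPase Rab9 (2.02 ± 0.32) and the kinesin Kif3b (2.00 ± 0.55) had the largest differences, followed by Mcat, Pym1, Trim32 and Asb8 (1.86 to 1.91), with adjusted p at most 0.0131. Gadd45g (-2.01 ± 0.56), Zfp951 (-1.87 ± 0.62), Obi1 (-1.71 ± 0.62) and Edem1 (-1.39 ± 0.50) were the 4 with a lower decay value (adjusted p at most 0.0468). Ythdf1 (1.25 ± 0.27), Ythdf2 (1.33 ± 0.26) and Ythdf3 (1.03 ± 0.34) fell less, with adjusted p = 3.55e-04, 1.06e-04 and 0.0265.

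Against the single knockouts 11 lists were called, and the 8 described held with an estimated correlation. Medians are relative to the 0.42 of all genes. Naive pluripotency genes were higher in 18 of 32 (21 adjusted over the list alone, median 0.17, camera adjusted p = 5.36e-06), with Esrrb at 1.25 ± 0.13 and Tdh, threonine dehydrogenase, at 0.55 ± 0.08. Core pluripotency genes were higher in 12 of 21 (14 adjusted over the list alone, median 0.11, camera adjusted p = 7.57e-05). Among them were Sall4 (1.06 ± 0.16) and L1td1 (0.70 ± 0.10). As in the comparison with WT, the list tests did not adjust for how fast a transcript falls. Feeder markers were lower as a list (0 of 25, 0 adjusted over the list alone, median -0.62, camera adjusted p = 6.73e-09), Ccn1 at -0.86 ± 0.40 and Tagln at -0.32 ± 0.16. Germline genes were lower as a list (0 of 13, 0 adjusted over the list alone, unshifted median 0.03, mean -0.12, camera adjusted p = 3.41e-04), Tuba3a at 1.39 ± 0.53 and Piwil2 at -1.56 ± 0.65. Ribosomal proteins were called as higher (73 of 81, 76 adjusted over the list alone, median -0.04, camera adjusted p = 4.58e-53), with Rpl4 and Rpl23 at 0.52 ± 0.04. So were protein synthesis factors (30 of 37, 32 adjusted over the list alone, median 0.00045, camera adjusted p = 2.25e-21), with Eef1b2 at 0.61 ± 0.05 and Eef1a1 at 0.41 ± 0.04. So were oxidative phosphorylation genes (41 of 75, 49 adjusted over the list alone, median -0.07, camera adjusted p = 2.33e-10), with Uqcr10 at 0.53 ± 0.07 and Ndufa2 at 0.71 ± 0.11. So were glycolysis genes (15 of 28, 17 adjusted over the list alone, median -0.10, camera adjusted p = 3.41e-04), with Slc2a1 at 0.91 ± 0.11 and Pkm at 0.27 ± 0.04. Under median and TMM scaling all but protein synthesis (no call) were called lower, at 4 h only ribosomal proteins. The naive, core and germline lists were not called under either scaling.

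The count was 1545, 1541 higher and 4 lower. Median scaling moved the median of all genes by -0.36 and gave 164 genes, 117 higher and 47 lower, TMM scaling gave 168, 117 and 51, and the count was 498 and 537 without Triple_KO replicate A and B, 164 at 4 h, 578 with a straight line and 2911 with edgeR. Without Triple_KO replicate A or B the calls of Kif3b, Mcat, Trim32, Asb8, Ythdf3, Zfp951, Edem1 and Obi1 ended, without A those of Gadd45g and Ythdf1, and without B that of Rabif. Among the single knockouts, calls ended for Zfp951 and for Edem1 and Obi1 without Ythdf1_KO replicate A and B respectively, for Edem1 and Obi1 without Ythdf2_KO replicate A, for Obi1 without Ythdf2_KO replicate B, for Ythdf3 and Edem1 without Ythdf3_KO replicate A, and for Zfp951, Edem1 and Obi1 without Ythdf3_KO replicate B. Genes with a long 3′ UTR stood 0.02 above the others while camera's direction was down (camera adjusted p = 0.0455). That call ended without either replicate of Triple_KO or Ythdf2_KO, without replicate B of Ythdf1_KO or Ythdf3_KO, and with median or TMM scaling, and the value turned to -0.037 with a pseudocount of 5 FPM.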

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

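The tests of the spread across genes above 20 FPM and of a few chromosome 13 genes, the use of the planned gene structure comparison to weigh the smaller fall in Triple_KO, and the splits that moved the 0 h and 8 h libraries together were chosen after the results were seen, and the others before.

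Ythdf3 stood apart in 1 of 40 groups of 4 libraries tested: in Ythdf2_KO at 8 h, library 2 of replicate B had 14.6 FPM and the others 9.03 to 9.93 FPM. Chance gives about 1 such group in 20. The change over 8 h differed between knockouts and WT in 4 genes (Ythdf1_KO), 16 (Ythdf2_KO), 30 (Ythdf3_KO) and 657 (Triple_KO), and between Triple_KO and the single knockouts in 1545, by limma's test of the difference itself.

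Most transcripts fell less over 8 h in Triple_KO than in WT, by a median of 0.37. Thinning every library to the shallowest left 0.364 of an unthinned 0.369, which argues against lower depth at 8 h in WT. The gap between short-lived regulators and ribosomal proteins, which a single factor for all genes moves only through the pseudocount, was -2.12 in the lower Triple_KO replicate and lay under the highest of the others, -1.81, as such a factor needs. The spread across genes above 20 FPM, 0.564 in the higher Triple_KO replicate against a lowest other of 0.662, argues against a single factor as the whole cause. Open are a weaker block of transcription (short-lived regulators changed by -0.357 from 4 to 8 h in the higher Triple_KO replicate, and by -0.48 and -0.28 in WT) and slower loss of transcripts whose structure favours m6A (few-junction genes 0.178 above the others, camera adjusted p = 0.357, but -0.16 without the filter), and loss of the readers itself, which the design names, may act through either.

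Fibroblast feeder markers were higher at 0 h in Triple_KO, 11 of 22 past the test, in cells that were plated on gelatin. Feeder fibroblasts in the cultures bring their matrix genes: the median change of the 5 collagens and proteoglycans measured was 0.772, 3 of them past the test, against a mean of 0.837 for Acta2 and Tagln, which is consistent with such cells. Col1a1 went from 16.2 to 38.4 FPM. S100a6, the most abundant marker at 183 FPM in WT, stood at -0.11, and Timp1 at 0.22, neither past the test. A change in the stem cells themselves stays open and was not tested.

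Genes of chromosome 13 stood 0.17 above all genes at 0 h in both Ythdf1_KO replicates. A few genes with large changes do not account for it, since the lower quartile was also raised, by 0.126 or more, and the middle of their distribution by 0.165 or more. An extra copy in part of the cells may account for it and stays open: at 4 h and 8 h the median ran from 0.0859 to 0.165 above all genes, and 2 of these 4 values, 0.0859 and 0.0973, lay under the 0.1 it needs in each. Over 3 parts of the chromosome the medians were 0.150, 0.139 and 0.189. Loss of Ythdf1 itself, which the design names, stays open and was not tested.

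Splits of the same libraries into groups of the same sizes were fitted on single libraries, so they bear on the chance division of libraries, and duplicates of one replicate are not independent. With the replicate as the unit, 2 against 2 make too few splits for a share under 0.05. At 0 h and in the WT time course 1 of the 35 splits, the real one, gave as many genes. The counts were 5447 against at most 0 in another split for the WT time course, 109 against 1 for Ythdf1_KO and 570 against 1 for Ythdf2_KO. They were 252 against 1 for Ythdf3_KO and 1758 against 0 for Triple_KO. Against the single knockouts 1 of 100 splits, the real one, gave as many, 1771 against 412. With 0 h and 8 h libraries split independently, some draws keep the 8 h genotypes whole, and with them part of the effect, so the share depends on the draw and was not used to decide on chance. As many genes came in 3 of 100 splits for Ythdf1_KO (real 2, highest other 20), 6 for Ythdf2_KO (5 and 173), 2 for Ythdf3_KO (51 and 93), 6 for Triple_KO against WT (1203 and 2364) and 2 against the single knockouts (1823 and 2273). Among splits that broke up the 8 h genotypes the highest counts were 20, 173, 48, 510 and 117, and with 2 of the 4 in each group 0, 2, 2, 0 and 1. The 20 and 173 came with 3 of the 4 libraries at 8 h kept together, and so with part of the genotype difference. With the 0 h and 8 h libraries moved together, 1 of 35 splits gave as many genes for Ythdf1_KO (2 against 0), Ythdf2_KO (5 against 1), Ythdf3_KO (51 against 0) and Triple_KO (1203 against 0), and 1 of 100 against the single knockouts (1823 against 15), so chance can be excluded for single libraries in Ythdf3_KO and both Triple_KO comparisons. It is left open in Ythdf1_KO and Ythdf2_KO, where leaving out a replicate gave 0 to 2 genes.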

How the results depend on the processing

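The fits on 1 transcript per gene chosen by its highest value, the edgeR fits on recovered reads, the count without chromosome 13 genes (200 in Ythdf1_KO at 0 h), the spread over genes above 20 FPM and the overlap of calls with WT replicates split were chosen after the data were seen, and the others were planned. Apart from fits that left out a replicate, gene results kept direction and side of the threshold in 3078 comparisons of a result with an alternative, lost the call in 297, gained one in 34 and turned direction in 34. For list results these numbers were 549, 115, 0 and 25. With a replicate left out, gene results kept both in 1226, lost the call in 169, gained one in 3 and turned in 22, and list results kept both in 303 and lost the call in 37. A lone replicate was assumed to vary like the other groups. Except where its construction shows it, for fewer samples or genes tested, the cause of a changed result was not tested.

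Labels share letters A and B. Deviations from group means did not correlate (-0.02 to 0.02, 10 pairs at 0 h). As A and B differed no more than duplicates, this cannot exclude pairing. With the letter as a replicate block the counts were 5175 in the WT time course, 242, 721, 396 and 1914 at 0 h against WT for Ythdf1_KO, Ythdf2_KO, Ythdf3_KO and Triple_KO, 2012 for Triple_KO against the single knockouts, and 4, 13, 33, 665 and 1560 for the decay values in the same order.

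Without the filter on low values the 0 h counts were 57, 312 and 102 in the single knockouts, and the decay counts 0 in Ythdf2_KO (limma, 1093 at an unadjusted p under 0.05, 32 with edgeR), 1 in Ythdf3_KO and 422 in Triple_KO. With a fit on all times the 0 h counts were 20, 141, 68 and 559, and 633 against the single knockouts. A pseudocount of 0.5 FPM, transcripts kept as deposited and the highest transcript per gene each left 1 gene in the Ythdf2_KO decay comparison. With libraries kept separate the decay counts were 55, 59 and 1154 in Ythdf2_KO, Ythdf3_KO and Triple_KO, and with edgeR 32, 74 and 1292, and 2911 against the single knockouts; edgeR put Ythdf2 in Ythdf3_KO at 0.072.

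Median and TMM scaling gave decay counts of 10 and 10 in Ythdf1_KO, 0 and 0 in Ythdf2_KO (limma, 449 and 442 at an unadjusted p under 0.05, 32 with edgeR), 14 and 4 in Ythdf3_KO, 160 and 152 in Triple_KO, and 164 and 168 against the single knockouts. Directions turned, with median and TMM scaling respectively, for Uqcrfs1 in the WT time course (0.11 and 0.18), Ythdf3 at 0 h in Ythdf2_KO (0.0011 and 0.0073) and the decay value of Ythdf2 in Ythdf3_KO (0.030 and 0.035). For Triple_KO decay values they turned for Rpl4 (-0.00062 and -0.0053) and Eef1a1 (-0.051 and -0.055), and against the single knockouts for Eef1a1 (-0.018 and -0.023) and Pkm (-0.15 and -0.16). Of lists, relative medians were 0.030 and 0.030 for protein synthesis factors (no call) and 0.077 and 0.077 for ribosomal proteins (called higher) in Ythdf2_KO. In Triple_KO they were -0.15 and -0.15 for ribosomal proteins, -0.053 and -0.054 for protein synthesis factors and -0.19 and -0.19 for oxidative phosphorylation. Against the single knockouts they were -0.10 and -0.10, -0.064 and -0.065 (no call) and -0.13 and -0.13 for these, and -0.16 and -0.16 for glycolysis, all others called lower.

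At 4 h in place of 8 h, 2802 genes changed in WT and Axl stood at -0.24. The decay counts were 0 in Ythdf1_KO (limma, 490 at an unadjusted p under 0.05, edgeR not run at 4 h), 2 in Ythdf2_KO, 1 in Ythdf3_KO, 141 in Triple_KO and 164 against the single knockouts. Directions turned in Ythdf1_KO for Slc2a1 (-0.0010), Ythdf2 (0.022), Ythdf3 (0.26), S100a6 (-0.31) and the feeder list (-0.037). In Ythdf2_KO they turned for Naca (0.13), Ythdf1 (0.42), Rpl41 (0.036), Rpl4 (0.064), Sgk1 (0.00044), Dusp1 (0.63), Pkm (0.0030) and glycolysis (0.00029). In Ythdf3_KO they turned for Ythdf2 (0.038), Hspd1 (0.031), Ccn1 (-0.56) and glycolysis (0.040). In Triple_KO they turned for Piwil2 (0.25), ribosomal proteins (-0.24) and oxidative phosphorylation (-0.21). In Triple_KO against the single knockouts they turned for Rpl23 (-0.0083), Ccn1 (0.0065), Piwil2 (0.62), ribosomal proteins (-0.22) and oxidative phosphorylation (-0.16). A straight line over the times gave 0, 0 and 0 genes in the single knockouts (limma, 240, 318 and 207 at an unadjusted p under 0.05, edgeR not run on the line), 183 in Triple_KO and 578 against the single knockouts.

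For gene structure, values are the median of a set less that of the other genes. Genes with few junctions turned without the filter, to 0.12 in the WT time course, -0.16 in Triple_KO decay values and -0.16 against the single knockouts. With median scaling, TMM scaling and 4 h they were called in Triple_KO (0.24, 0.24 and 0.27) and against the single knockouts (0.19, 0.19 and 0.18). Genes with a long 3′ UTR were called in the WT time course with these 3 (-0.38, -0.38 and -0.25). Against the single knockouts their call ended with these 3 (0.050, 0.049 and 0.085), with a pseudocount of 0.5 FPM (0.038), without the filter (0.019) and with a straight line (0.022), and the value turned with a pseudocount of 5 FPM (-0.037). Genes with a long internal exon turned with a pseudocount of 5 FPM in Triple_KO (-0.0036) and against the single knockouts (-0.037), in the latter also without the filter (-0.0041), and with an estimated correlation they were called there (0.042).

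With the WT replicates split between the pair, correlations of knockout effects at 0 h were 0.20, 0.14, 0.22, 0.25, 0.27 and 0.13 for Ythdf1_KO with Ythdf2_KO, Ythdf3_KO and Triple_KO, Ythdf2_KO with Ythdf3_KO and Triple_KO, and Ythdf3_KO with Triple_KO. For decay values they were -0.011, -0.010, 0.039, 0.020, 0.019 and 0.013 in the same order. Ythdf2_KO and Triple_KO then shared 115 higher and 86 lower genes at 0 h, or 110 and 80 with WT replicates A and B exchanged (40 and 31 opposite), and Ythdf3_KO and Triple_KO 51 and 34, or 38 and 26 (48 and 31 opposite). By construction the split removes the shared WT libraries, but not a deviation common to both WT replicates.

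With 1 replicate left out at a time, the 0 h counts ran from 105 to 218 in Ythdf1_KO, 349 to 551 in Ythdf2_KO, 173 to 336 in Ythdf3_KO, 1129 to 1508 in Triple_KO and 1042 to 1969 against the single knockouts. The decay counts ran from 0 to 2 in Ythdf1_KO and 0 to 2 in Ythdf2_KO (limma; where 0, 465 without Ythdf1_KO replicate B, and 487, 634 and 504 in Ythdf2_KO without WT replicate A, WT replicate B and Ythdf2_KO replicate A, at an unadjusted p under 0.05; edgeR, on all replicates, 4 and 32), 6 to 14 in Ythdf3_KO, 183 to 421 in Triple_KO and 498 to 1512 against the single knockouts. Reader values that turned ran at 0 h from -0.067 to 0.063 (Ythdf1) and -0.13 to 0.55 (Ythdf3) in Ythdf1_KO, -0.26 to 0.022 (Ythdf1) and -0.37 to 0.31 (Ythdf3) in Ythdf2_KO, and -0.33 to 0.017 (Ythdf1), -0.094 to 0.19 (Ythdf2) and -0.26 to 0.43 (Ythdf3) in Ythdf3_KO. For Ythdf3 they ran from -0.42 to 0.27 in Triple_KO and -0.42 to 0.094 against the single knockouts. Decay values that turned ran from -0.61 to 0.072 (Ythdf3) in Ythdf1_KO, -0.31 to 0.033 (Ythdf1) and -0.051 to 0.63 (Ythdf3) in Ythdf2_KO, and -0.22 to 0.28 (Ythdf1), -0.31 to 0.26 (Ythdf2) and -0.31 to 0.37 (Ythdf3) in Ythdf3_KO. Against the single knockouts genes with a long internal exon ran from 0.021 to 0.060, called without Ythdf1_KO replicate A, and genes with a long 3′ UTR from 0.0017 to 0.032. Depth limits the values of the readers: Ythdf2 had 6 to 15 reads per WT library at 8 h.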

Other observations

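The 3 tests in this part were written before their results were seen.

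Genes were put in 5 groups by the mean decay value of the single knockouts, with which neither Triple_KO nor WT shares a library. From the group that fell most to that which fell least, the median difference of Triple_KO and WT decay values was 0.65, 0.55, 0.41, 0.31 and 0.18, and the median change at 0 h was 0.14, 0.10, 0.07, 0.05 and 0.02.

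Whether the 0 h changes of Triple_KO are those of transcripts that are short-lived was left undecided: across genes, which are not independent replicates, Spearman's rho of that change with the mean decay value of the single knockouts was -0.0797 and Pearson's r -0.0361. The sum of the single-knockout effects does not account for all of the 0 h changes of Triple_KO, since 658 genes differed from it, 350 above and 308 below, among them 314 of the 1906 changed genes. The others of the 1906 were not shown to depart from it (median SE of the difference 0.41), and across genes, with WT libraries shared, Pearson's r of the effect and the sum was 0.578. Gain or loss of whole chromosomes does not account for them either, since no chromosome with 50 or more tested genes stood more than 0.0557 from all genes in both replicates.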
